A study of Mus musculus with 12 samples.

How the data were processed

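Gene expression was measured on Affymetrix GeneChip arrays in 12 samples of sorted mouse blood cells, with total RNA from C57Bl/6 mice aged 10 to 12 weeks, per the labels. The groups were haematopoietic stem cells (HSC, 3 arrays), multipotent progenitors (MPP, 3 arrays), PreMegE progenitors (4 arrays) and splenic CD4+ T cells (2 arrays). The group and replicate number of each array came from its title. The fourth PreMegE array carries the number 3 in its description, so averaging PreMegE replicates 3 and 4 as 1 sample was among the alternatives. HSC and MPP were sorted for this study, whereas the PreMegE and CD4+ T cell arrays came from 2 earlier studies, per the series design text. Study and group therefore cannot be told apart in any comparison across those sets. The labels do not say that replicates came from separate animals, so the p-values measure the spread between these samples.

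The deposited values are 1 intensity per probe set, summarised with RMA per the submitters' processing notes, which give no version and do not say which arrays were normalised together. All values were positive and array medians lay between 14.4 and 15.6, so the scale is linear. The planned design assumed log2 values and foresaw this case, and log2 was taken here before every test, with no further normalisation and no filter on low values. It covered 45101 probe sets. The 64 control probe sets were left out of all tests. Names came from the platform annotation, which gave 34945 probe sets a single gene symbol, 932 several and 9160 none. Of the probe sets with a single symbol, 34741 had a gene ID in the RefSeq annotation of assembly GRCm38.p6, which changed 0 symbols and was used for names and for chromosomes only. Probe sets with several symbols or none were not named. A gene was represented by its probe set with the highest mean over the 12 arrays. This gave 18194 genes, of which 9009 had more than 1 probe set.

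Differences were tested with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table for reading. A single lmFit model with a mean per group was fitted to all 12 arrays, followed by eBayes, two-sided tests and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05, and "rose", "fell", "higher" and "lower" in counts refer to called genes. The number that also differed at least 2-fold is given beside each count. The CD4+ T cell group has 2 arrays and borrows most of its estimate of spread from the other groups. Genes highest in a population had to be called and at least 2-fold higher there than in each of the other populations. As these comparisons share arrays, that number was set beside 20 simulations of unchanged groups and beside the overlap of independent lists. No detection limit was applied to the deposited values. Whether the lower mean of a gene lay under the lower quartile over genes of its group was recorded after the values were seen. For arrays, the number of arrays limits the precision of every value. Pearson correlations between arrays are across genes, which are not independent replicates.

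Gene lists were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the 26 lists of each comparison, and again with the correlation estimated from the data. The lists held 768 genes, of which 712 were measured. They were HSC-associated genes, lymphoid priming, granulocyte-monocyte, megakaryocyte, erythroid, T cell, B cell, NK and cytotoxic, macrophage, mature neutrophil, mast cell with basophil and eosinophil, stroma and endothelium, mitosis, DNA replication, cell-cycle inhibitors and quiescence, imprinted genes, Hox clusters and cofactors, developmental regulators of non-blood tissues, Polycomb and Trithorax, DNA methylation, ribosome biogenesis, oxidative phosphorylation, glycolysis, immediate early and heat shock, interferon response, and sex-linked genes. Some genes belong to more than 1 list. Members of a list were also called with p-values adjusted over the list alone. RNA quality was described by the log2 ratio of the 3' to the 5' control probe set of beta-actin and of Gapdh.

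The genes named followed a rule. It took the genes behind the sort markers, and per comparison the 6 largest rises and 6 largest falls among called genes whose arrays did not overlap between the groups. Clone names, gene models and the sort markers were left out of these 12. Up to 4 called members of lists that passed and up to 2 of other lists with the largest change were added. Where a list had no called member, the 2 with the smallest p were taken. The 8 genes that most set a population apart and called members of 15 fixed lineage regulators completed the names. Ly6a and Klrb1c, which encode Sca1 and NK1.1, had no probe set named for them alone and were not analysed here. The groups, comparisons, tests, lists, this rule and all alternatives other than the 3 described next were fixed before the data were examined. The alternatives added after seeing the data were HSC replicate 1 as the lone HSC array, leaving out genes of the X and Y chromosomes, and leaving out HSC replicate 2 together with PreMegE replicate 1.

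The alternatives fixed beforehand were quantile normalisation of all arrays again, cyclic loess, leaving out the genes with the lowest means, the mean of all probe sets of a gene, probe sets without the suffixes _s_at and _x_at, each probe set on its own, the gene's next brightest probe set, eBayes with trend and robust settings, array weights, the replicate number as a block, PreMegE replicates 3 and 4 averaged, only the 2 groups compared, a 2-fold minimum, camera with an estimated correlation, and leaving out each array in turn. The same pipeline was tested on simulated data in which the groups had equal means apart from known changes. Of 50 genes changed 2-fold per comparison it recovered 88.0% in MPP against HSC, 94.0% in PreMegE against HSC, 94.0% in PreMegE against MPP and 74.0% in CD4+ T cells against HSC. For 1.5-fold changes the shares were 20.0%, 26.0%, 16.0% and 18.0%. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.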

Results

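Gene expression was compared between 4 populations of sorted mouse blood cells on 12 arrays. Bone marrow gave HSC (3 arrays), MPP (3 arrays) and PreMegE cells (4 arrays), and spleen gave CD4+ T cells (2 arrays). HSC were sorted as lineage-negative Kit+ Sca1+ cells with CD150 and without Flt3, and MPP as their counterparts without CD150 and with Flt3. PreMegE cells, which are known as early progenitors of platelet-forming and red blood cells, lacked Sca1, CD105 and CD41 and carried Kit and CD150. Intensities had medians of 14.4 to 15.6 and upper quartiles of 63.0 to 80.2 per array. Levels are given as mean log2 intensity ± SD, and differences as log2 fold changes ± SE. Lower quartiles over genes were 3.27 to 3.35 per population. A mean under that level may not lie above background, so a difference from it is not an exact fold and gives no order among genes. It is stated below mainly for the largest changes and for genes highest in a population. Other named genes lay under it too, among them Thbs1 and Pou2af1 in HSC, Gp1bb and Nupr1 in MPP, and Hoxb5 and Gfi1 in PreMegE. Replicate arrays correlated across genes at r of 0.985 to 0.988 within HSC, 0.994 within MPP, 0.984 to 0.992 within PreMegE and 0.985 within CD4+ T cells. HSC and MPP arrays correlated at 0.968 to 0.978, PreMegE with HSC arrays at 0.945 to 0.961, and CD4+ T cell arrays with those of any other population at 0.867 to 0.893.

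**Figure D1:**
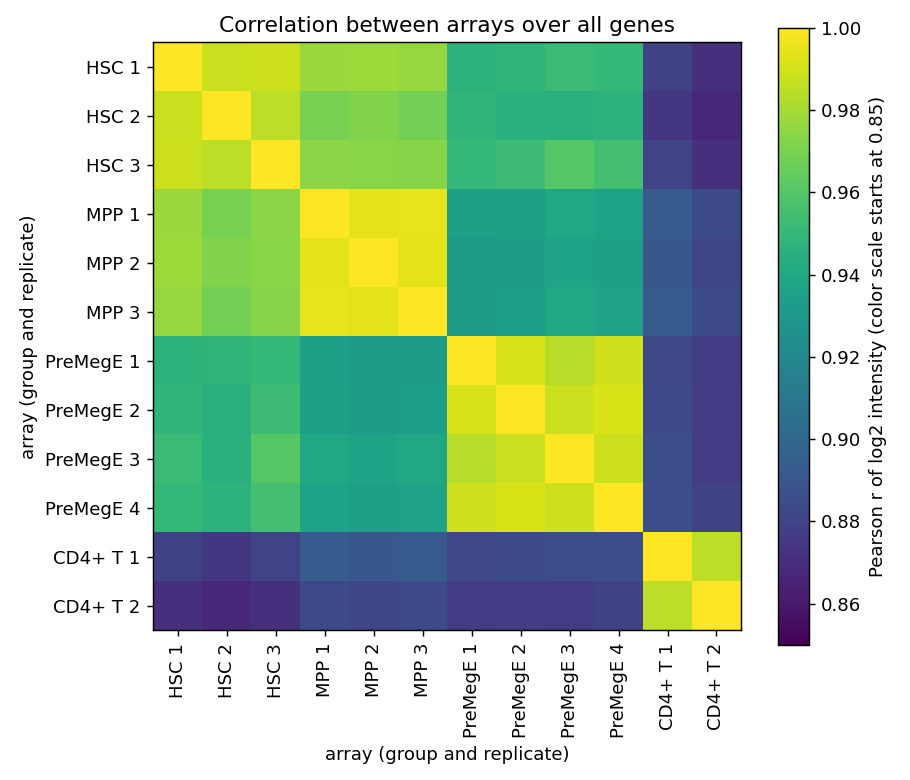
Pearson correlation across 18194 genes between every pair of the 12 arrays, from log2 intensities. HSC and MPP arrays lay closest to each other (0.968 to 0.978) and CD4+ T cell arrays farthest from the rest (0.867 to 0.893).

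Transcripts of the sort markers came first, as a check of the labels. Flt3 was at 10.02 ± 0.08 in MPP (n = 3), 6.60 ± 0.24 in HSC (n = 3), 5.92 ± 0.52 in PreMegE (n = 4) and 5.73 ± 0.11 in CD4+ T cells (n = 2). Slamf1, which encodes CD150, was at 6.83 ± 0.20 in HSC, 3.72 ± 0.17 in MPP, 6.82 ± 0.19 in PreMegE and 7.16 ± 0.12 in CD4+ T cells. Its change from HSC to PreMegE was -0.01 (adjusted p = 0.986), where the gene's next brightest probe set gave 0.79 (adjusted p = 0.0454). Itga2b, which encodes CD41, was at 10.54 ± 0.09 in HSC, 7.82 ± 0.11 in MPP, 8.45 ± 0.29 in PreMegE and 5.09 ± 0.26 in CD4+ T cells. Kit was between 9.97 and 10.58 in the 3 marrow populations and at 3.46 ± 0.81 in CD4+ T cells. Kit did not pass between PreMegE and HSC (-0.56, adjusted p = 0.119). It passed there without PreMegE replicate 3 (adjusted p = 0.0484) and without CD4+ T cell replicate 1 or 2 (0.0476 each), and its next brightest probe set gave 1.03. With that probe set Kit was called higher in PreMegE than in HSC (adjusted p = 5.2e-04). Cd4 was at 9.30 ± 0.27 in CD4+ T cells and at 4.76 to 4.89 elsewhere. Cd8a did not differ detectably in CD4+ T cells against HSC (-0.10, adjusted p = 0.735), while Cd8b1 rose by 2.32 ± 0.20 to 5.25. Eng, which encodes CD105, did not pass between PreMegE and HSC (0.19, adjusted p = 0.604). Ptprc, whose B220 isoform was a sort marker, rose by 2.12 ± 0.20 in CD4+ T cells. Flt3 changed by -0.68 in PreMegE against HSC (adjusted p = 0.0330), a call that ended without HSC replicate 2 (0.129) or 3 (0.0786), or PreMegE replicate 3 (0.0574) or 4 (0.0648), under quantile normalisation (0.0948), and with PreMegE replicates 3 and 4 averaged (0.0508). It changed by -0.87 in CD4+ T cells against HSC, which ended without HSC replicate 2 (0.0592) or CD4+ T cell replicate 1 (0.0979).

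The comparison of MPP with HSC asks which transcripts change as stem cells lose long-term self-renewal. Dntt, the DNA polymerase that adds nucleotides to antigen receptor genes in early lymphocytes, rose by 6.83 ± 0.24 to 11.92 ± 0.09 in MPP (n = 3 against 3, adjusted p = 1.3e-10). The chemokine genes Ccl3, Ccl9 and Cxcl2 rose by 5.41 ± 0.19, 5.02 ± 0.26 and 4.58 ± 0.30. Bpifc, of the lipid-binding BPI family, rose by 4.58 ± 0.17 and Emp1, an epithelial membrane protein, by 4.45 ± 0.24. Falls included Vwf (-4.41 ± 0.21), the platelet adhesion protein von Willebrand factor, Cavin2 (-4.35 ± 0.32), a coat protein of caveolae, and Car1 (-4.03 ± 0.24), a carbonic anhydrase of red cells. Pf4 (-4.02 ± 0.22), the platelet chemokine, Mfsd2b (-3.78 ± 0.19), a sphingosine-1-phosphate exporter of red cells and platelets, and Aqp1 (-3.74 ± 0.22), a water channel, followed. None of these 12 genes overlapped between the 3 MPP and 3 HSC arrays, which was a condition for naming them and which chance alone gives to 10% of genes. For 4 of them (Ccl3, Bpifc, Emp1 and Cavin2) the lower mean was under the lower quartile.

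**Figure D2:**
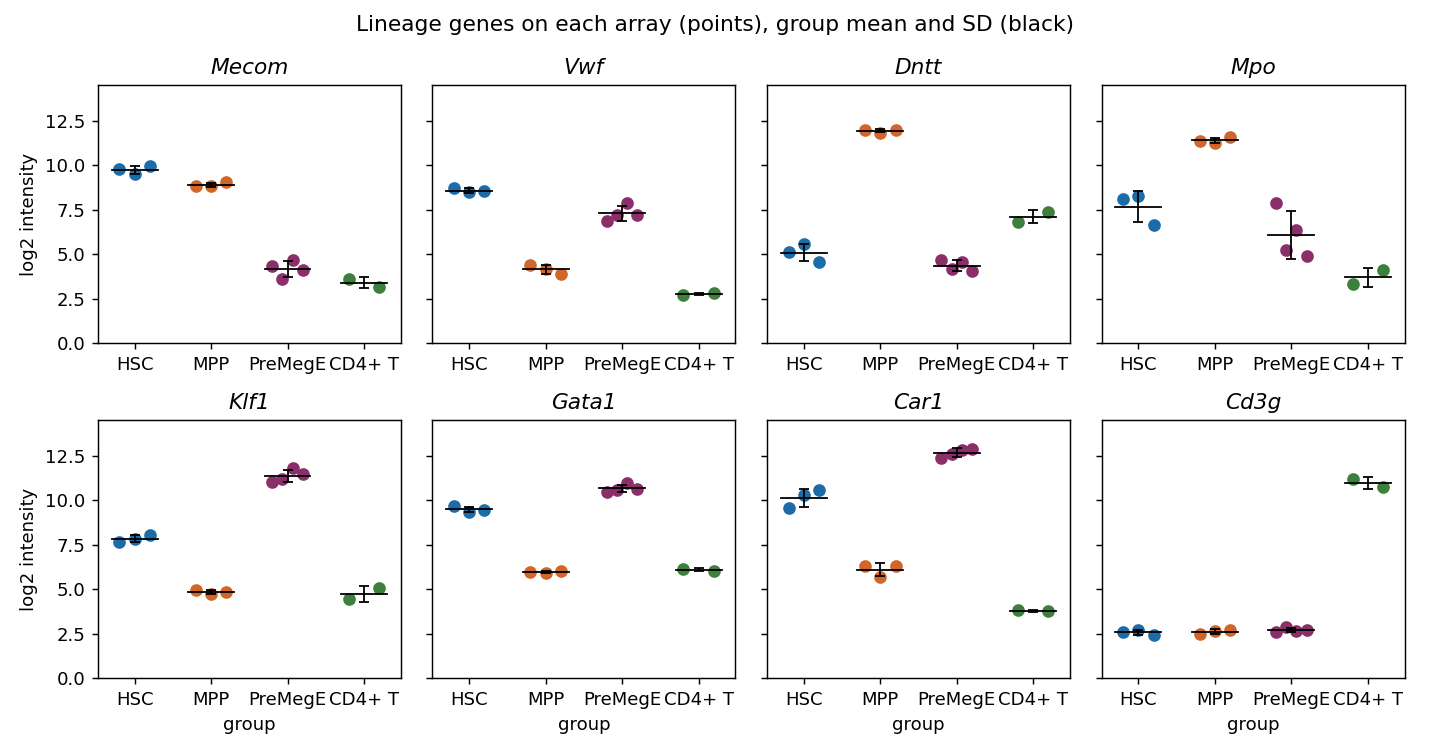
Log2 intensity of 8 lineage genes on each array (points) with group means and SD bars, by population. Mecom and Vwf were highest in HSC, Dntt and Mpo in MPP, Klf1, Gata1 and Car1 in PreMegE and Cd3g in CD4+ T cells.

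Of 18194 genes, 2058 (11.3%) were called between MPP and HSC, with 1161 higher and 897 lower in MPP, and 855 differed at least 2-fold (465 higher and 390 lower). The share of higher genes was 56.4%, and 44.4% after quantile normalisation or 46.8% after cyclic loess, so no side was favoured under every scaling. Without MPP replicate 3, 1280 genes were called. Gata1 (-3.52 ± 0.15), Klf1 (-2.98 ± 0.21), Gata2 (-1.52 ± 0.14) and Tal1 (-1.15 ± 0.17), which drive red cell and platelet genes, fell. Cebpa (2.25 ± 0.21) and Spi1 (1.04 ± 0.21), of the myeloid programme, and Ikzf1 (1.30 ± 0.18), of the lymphoid programme, rose. Gata2 did not pass on its next brightest probe set (-0.73) and Ikzf1 gave -0.02 there. The call of Gata3 (-0.54 ± 0.14) ended without HSC replicate 2 (adjusted p = 0.0540) or 3 (0.0527), or MPP replicate 2 (0.0762) or 3 (0.0604).

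In the fixed lists, counts are genes called over the genome, with the counts adjusted over the list alone beside them where they differ. Of 34 HSC-associated genes, 0 rose and 23 fell (1 and 26 adjusted over the list alone), with camera adjusted p = 2.7e-19. Fhl1, a LIM-domain protein, fell by 2.15 ± 0.19, the transglutaminase gene Tgm2 by 2.11 ± 0.30 and the stress-induced cofactor Nupr1 by 1.98 ± 0.16. Of 24 lymphoid priming genes 16 rose and 1 fell (16 and 2, 6.1e-15), led after Dntt by the chromatin organiser Satb1 (4.12 ± 0.18), the immunoglobulin gene Ighm (4.09 ± 1.25) and the tetraspanin Cd53 (3.82 ± 0.24). Ighm was at 9.04 on HSC replicate 2 against 5.04 and 4.71 on replicates 1 and 3, and without HSC replicate 2 it rose by 5.47. The call of Ighm (adjusted p = 0.0479) ended without HSC replicate 1 (0.165) or 3 (0.157), MPP replicate 1 (0.125), 2 (0.0971) or 3 (0.146), PreMegE replicate 2 (0.0527), 3 (0.0521) or 4 (0.0524), or CD4+ T cell replicate 1 or 2 (0.0528 each), and under both scalings (0.0663 each). Of 24 granulocyte-monocyte genes 15 rose and 0 fell (18 and 0, 2.2e-16). Among them were the granule proteases and enzymes Ctsg (3.78 ± 0.42) and Mpo (3.72 ± 0.59), the adhesion molecule Emb (3.81 ± 0.27) and the regulator Irf8 (3.41 ± 0.25). Of 27 megakaryocyte genes 1 rose and 17 fell (1 and 20, 6.4e-16), including the platelet receptor gene Gp1bb (-3.47 ± 0.20), and Thbs1 (2.99 ± 0.21), a thrombospondin of platelet granules, rose. Of 35 erythroid genes 0 rose and 18 fell (1 and 20, 1.2e-14). These 5 lists also passed with an estimated correlation, at adjusted p-values of 5.9e-04, 5.9e-04, 0.00871, 0.00220 and 0.00769.

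Of 27 immediate early and heat shock genes 19 rose and 0 fell in MPP (5.2e-19, and 0.0234 with an estimated correlation). After Cxcl2 the largest rises were the stress-response factor Atf3 (4.29 ± 0.25), the nuclear receptor Nr4a1 (3.80 ± 0.49) and the transcription factor Klf4 (3.65 ± 0.34). The list's median level was 10.3 to 10.5 on the MPP arrays and 8.87, 8.55 and 7.77 on HSC replicates 1 to 3, and such genes respond to handling of cells within minutes. Heat shock members, chosen after their values were seen, were not called. Hspa1a was at 3.92, 9.34 and 9.20 on HSC replicates 1 to 3 and at 6.14 to 6.99 in MPP, and Hspa1b at 5.49, 11.15 and 11.56 and at 8.53 to 8.84. Hsph1 (9.15 to 9.39 in MPP, 9.36 to 10.13 in HSC) and Dnajb1 (12.46 to 12.58 and 12.56 to 12.59) differed less between HSC arrays. Nr4a1, Gadd45b (3.59 ± 0.24) and Btg2 (1.84 ± 0.29) belong both to this list and to the cell-cycle inhibitors and quiescence genes, where Cdkn1a, which encodes the cyclin kinase inhibitor p21, rose by 3.51 ± 0.32. Of these 23 inhibitor and quiescence genes 8 rose and 1 fell (8 and 2, 0.00805, adjusted p = 0.139 with an estimated correlation), and the list did not pass without HSC replicate 2 (0.0580). Of 23 imprinted genes 0 rose and 6 fell (0 and 7, 0.00115, adjusted p = 0.0967 with an estimated correlation). These included the adaptor Grb10 (-2.08 ± 0.17), the growth suppressor Ndn (-1.82 ± 0.16), the non-coding RNA Meg3 (-1.73 ± 0.27) and the cyclin kinase inhibitor Cdkn1c (-1.63 ± 0.23).

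Of 35 ribosome biogenesis genes 2 rose and 2 fell (3 and 3, 0.0149, adjusted p = 0.530 with an estimated correlation), including Pno1 (1.18 ± 0.26) and Nolc1 (0.72 ± 0.17), both of the nucleolus. Of 58 oxidative phosphorylation genes 7 rose and 0 fell (0.00805, adjusted p = 0.530 with an estimated correlation), led by the respiratory chain genes Uqcrfs1 (1.08 ± 0.19) and Cyc1 (0.82 ± 0.17). Neither list passed under quantile normalisation (0.170 and 0.159), under loess (0.187 each), with the lowest genes left out (0.0919 and 0.0735) or without HSC replicate 2 (0.0837 and 0.0717), and oxidative phosphorylation did not pass without MPP replicate 1 (0.0537). Of 17 mature neutrophil genes 1 rose and 2 fell (0.0402, adjusted p = 0.702 with an estimated correlation). The granule protein gene Ngp fell by 2.89 ± 0.70 and the chitinase-like Chil3 by 2.82 ± 0.72, while Padi4, a histone-modifying enzyme of neutrophils, rose by 1.21 ± 0.27. On HSC replicate 2 Ngp was at 11.01 against 8.20 and 7.84 on replicates 1 and 3 and Chil3 at 8.06 against 5.26 and 5.22, while Padi4 was at 4.88 against 6.10 and 4.95. Without this array the list did not pass (0.573). The list also failed to pass without MPP replicate 1 (0.0537) or 3 (0.0717), PreMegE replicate 3 (0.0534) or either CD4+ T cell array (0.0733), under quantile normalisation (0.120), and with PreMegE replicates 3 and 4 averaged (0.0571).

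The remaining lists did not pass between MPP and HSC. Of 37 T cell genes 10 rose and 1 fell (11 and 2, adjusted p = 0.0561). This list passed under quantile normalisation (0.0202), loess (0.0344), and without HSC replicate 1 (0.0481) or 2 (0.0134) or MPP replicate 3 (0.0451). Of 31 Hox genes and cofactors 0 rose and 4 fell (0.0561), including Hoxb5 (-1.27 ± 0.22). The Hox list passed without HSC replicate 1 (0.0481) or MPP replicate 2 (0.0269) and with the mean of all probe sets (0.00782). It also passed with the replicate number as a block (0.0487) and with the lowest genes left out (0.0458). Of 39 mitosis genes 2 rose and 6 fell (2 and 8, 0.226), including the spindle genes Kif23 (1.19 ± 0.26) and Hmmr (-1.10 ± 0.15). The mitosis list passed under quantile normalisation (0.0277), loess (0.0340) and without HSC replicate 2 (0.0134). DNA replication had 1 of 43 higher and 3 lower (0.789), with a median of 0.10 and a mean of -0.01. Glycolysis had 3 of 18 higher and 0 lower (0.137), led by Pgam1 (0.88 ± 0.16). Macrophage genes had 4 of 20 higher and 0 lower (5 and 1, 0.579), with a median of -0.15 and a mean of 0.06, led by the receptor Csf1r (1.67 ± 0.32). The macrophage list passed upwards with HSC replicate 1 as the lone HSC array (3.9e-04), its mean excess over other genes being 0.53 there and 0.05 with all arrays. The T cell list passed in that fit too (0.0201), while oxidative phosphorylation (0.201) and mature neutrophil genes (0.528) did not. B cell genes had 1 of 23 higher and 1 lower (1 and 0, 0.844), NK and cytotoxic genes 1 of 16 higher and 0 lower (2 and 0, 0.595), and mast cell, basophil and eosinophil genes 0 of 15 higher and 1 lower (0.397). Stroma and endothelium genes had 1 of 19 higher and 2 lower (0.335), including the proteoglycan Bgn (-1.69 ± 0.22). Polycomb and Trithorax genes had 3 of 39 higher and 5 lower (3 and 6, 0.564), with Asxl1 changed by -1.19 ± 0.16, and DNA methylation genes had 0 of 14 higher and 2 lower (0.538). Interferon response genes had 4 of 31 higher and 1 lower (7 and 3, 0.353), including the GTPase Igtp (-0.91 ± 0.17). Developmental regulators of non-blood tissues had 1 of 36 higher and 0 lower (0.789), the member being Hnf4a (1.05 ± 0.16), a liver factor, and 34 to 35 of the 36 lay below the median gene in every population.

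The sex-linked list had 1 of 4 higher and 2 lower in MPP (adjusted p = 0.267), with a median of -1.49, a mean of -0.09 and a downward test, and it passed without HSC replicate 1 (0.0190). Xist, the RNA that silences the second X chromosome of females, was at 12.04 on HSC replicate 1, at 2.45 and 2.59 on replicates 2 and 3, and at 10.91 or more on all arrays of the other populations. The Y-linked genes Eif2s3y and Kdm5d were at 7.46 and 6.02 on HSC replicate 2 and at 8.47 and 5.68 on replicate 3, and Eif2s3y was at 2.31 on replicate 1. The calls of Xist (6.30 ± 1.66) and Eif2s3y (-3.69 ± 1.00) ended when HSC replicate 2 or 3 or any MPP array was left out, at adjusted p-values of 0.0634 to 0.113 and 0.0729 to 0.119. With HSC replicate 1 as the lone HSC array 779 genes were called between MPP and HSC, of which 725 were among the 2058.

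Some calls of genes named for MPP against HSC ended with fewer arrays or on another probe set. Without MPP replicate 3 Ngp changed by -2.35 (adjusted p = 0.0811), and without MPP replicate 1 Nolc1 changed by 0.63 (0.0622). Chil3 changed by -1.88 without HSC replicate 2 (0.0817), -2.61 without MPP replicate 1 (0.0774) and -2.40 without MPP replicate 3 (0.0972). On the next brightest probe set Emp1 (0.32), Fhl1 (-0.03), Gp1bb (-0.06), Thbs1 (0.41), Grb10 (-0.13), Meg3 (-0.22) and Kif23 (0.04) did not pass. That probe set gave 0.22 for Asxl1, -0.46 for Nolc1 and -0.39 for Hnf4a, opposite to the values above. With HSC replicate 1 as the lone HSC array the spread comes from the other groups, and fewer arrays alone can end a call. There, among others, Padi4 (0.42, adjusted p = 0.554), Ngp (-2.08, 0.149), Chil3 (-1.90, 0.272), Meg3 (-1.34, 0.0543) and Spi1 (0.71, 0.237) did not pass. Pno1 (1.17, 0.0823), Nolc1 (0.65, 0.215) and Cyc1 (0.67, 0.145) did not pass either.

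**Figure D3:**
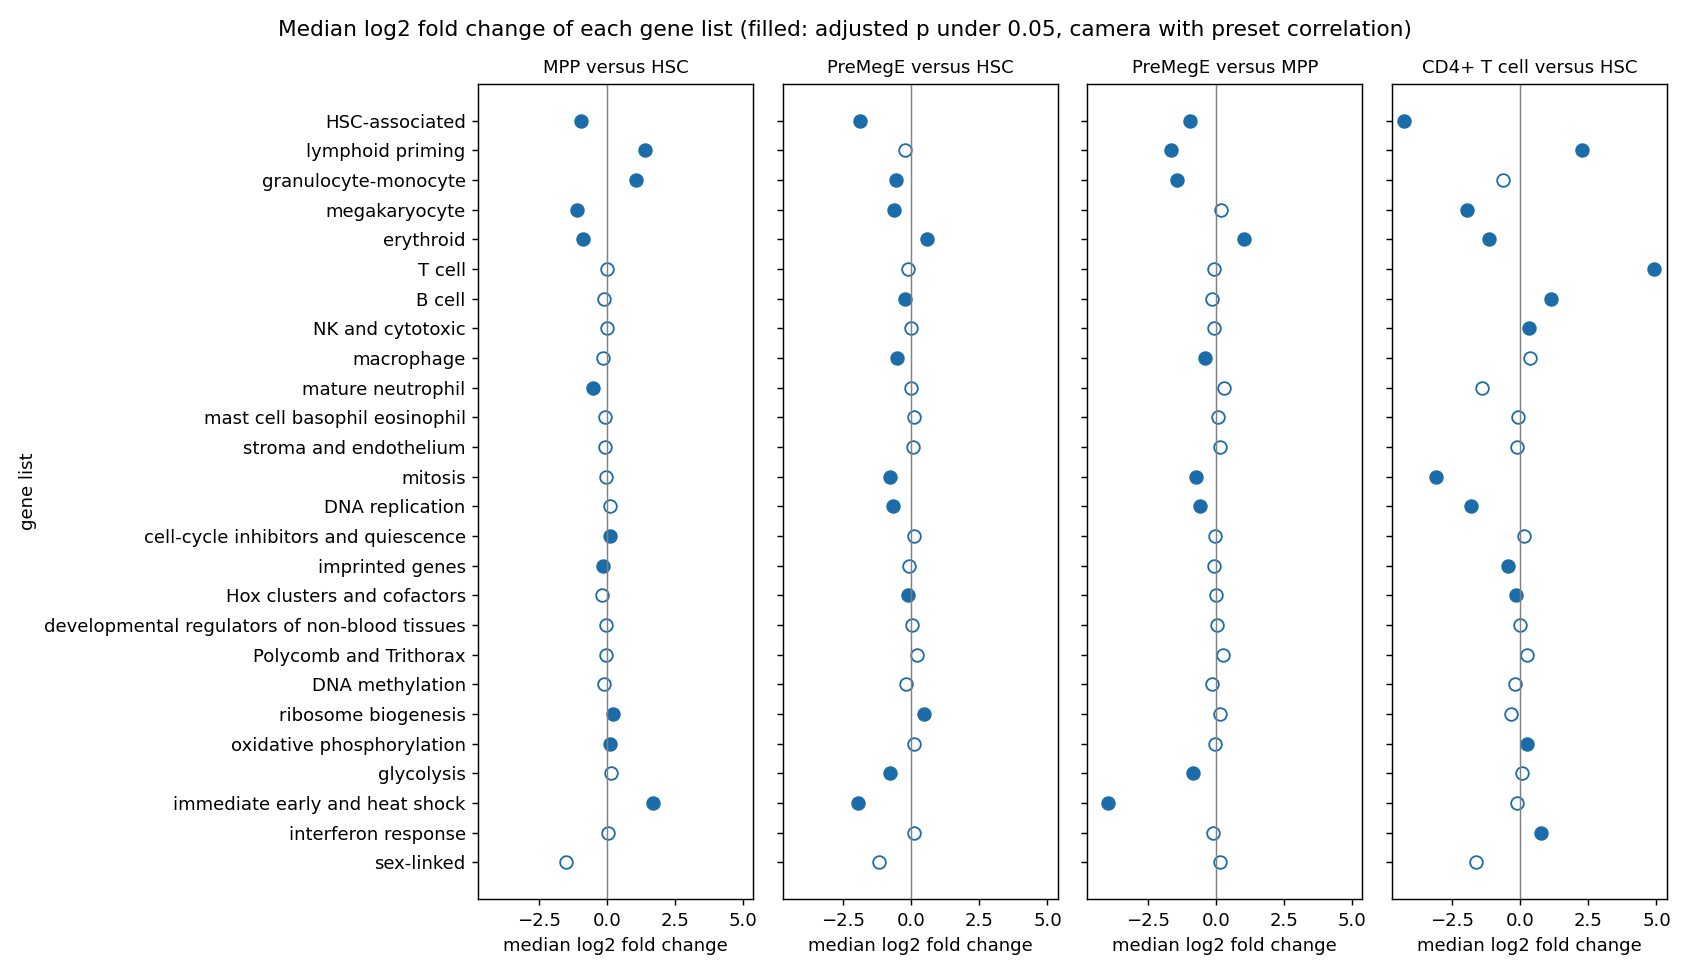
Median log2 fold change of the members of each of the 26 gene lists in the 4 comparisons, with filled symbols for lists that passed camera. Immediate early and heat shock genes had medians of 1.69 in MPP against HSC and -3.97 in PreMegE against MPP.

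The comparison of PreMegE cells with HSC follows the path towards platelets and red cells. The phospholipase-like Gdpd3 rose by 5.80 ± 0.25 to 9.93 ± 0.17 (n = 4 against 3, adjusted p = 3.0e-10), the sialyltransferase gene St8sia6 by 5.31 ± 0.34 and the meiotic recombination gene Rec114 by 4.35 ± 0.22. The secretory granule lectin Zg16 rose by 4.19 ± 0.17, the carboxylesterase Ces2g by 4.06 ± 0.15 and Scin, which severs actin filaments, by 3.94 ± 0.25. Falls included Fos (-7.26 ± 0.36), an immediate early transcription factor, Fscn1 (-6.22 ± 0.29), which bundles actin, and Mmrn1 (-5.77 ± 0.17), a protein of platelet granules. Tgm2 (-5.76 ± 0.28), Mecom (-5.55 ± 0.21), a transcription factor that stem cells require, and Procr (-5.51 ± 0.14), a surface receptor used to isolate stem cells, followed. For Rec114, Fscn1 and Procr the lower mean was under the lower quartile. Of all genes 5255 (28.9%) were called, 2167 higher and 3088 lower in PreMegE, and 2095 differed at least 2-fold (765 higher and 1330 lower). With HSC replicate 1 as the lone HSC array 3395 were called, 3238 of them among the 5255. The PreMegE arrays came from an earlier study, and their 3' to 5' log2 ratio of beta-actin was 3.88 ± 0.52 against 2.61 ± 0.18 in HSC, 2.52 ± 0.16 in MPP and 1.06 ± 0.10 in CD4+ T cells. The ratio of Gapdh was 3.67 ± 0.53 in PreMegE, 4.02 ± 0.15 in HSC, 3.74 ± 0.13 in MPP and 2.60 ± 0.08 in CD4+ T cells. The control probe set of 18S RNA was at 10.59 in PreMegE, 8.88 in HSC, 9.47 in MPP and 13.17 in CD4+ T cells, and the poly-A spike dap at 11.08, 9.36, 9.60 and 12.84.

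Of 34 HSC-associated genes 0 rose and 30 fell in PreMegE (1 and 32, camera adjusted p = 1.4e-25, and 4.1e-04 with an estimated correlation), including the stem cell transcription factor Hlf (-5.22 ± 0.16). This was the only list of the comparison that passed with an estimated correlation. Of 35 erythroid genes 19 rose and 1 fell (20 and 2, 3.4e-08, adjusted p = 0.0561 with an estimated correlation). The master regulator Klf1 rose by 3.54 ± 0.19, the blood group genes Ermap and Kel by 3.35 ± 0.25 and 3.18 ± 0.22, Mfsd2b by 3.18 ± 0.18 and Gata1 by 1.18 ± 0.14. Of 27 megakaryocyte genes 1 rose and 16 fell (2 and 17, 3.5e-06, adjusted p = 0.0561 with an estimated correlation). Falls included the myosin kinase Mylk (-4.29 ± 0.24), the platelet integrin Itgb3 (-4.26 ± 0.28), Pf4 (-4.16 ± 0.21) and the tetraspanin Cd9 (-2.16 ± 0.14). Of 27 immediate early and heat shock genes 0 rose and 23 fell (0 and 25, 2.1e-14, adjusted p = 0.0733 with an estimated correlation), including Fosb (-5.31 ± 0.22), Jun (-5.21 ± 0.23) and the phosphatase Dusp1 (-4.76 ± 0.24). The median level of this list was 5.02 to 5.40 on the PreMegE arrays.

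Of 39 mitosis genes 1 rose and 24 fell (2 and 25, 1.1e-07, adjusted p = 0.380 with an estimated correlation), and of 43 DNA replication genes 1 rose and 21 fell (2 and 29, 6.1e-07, adjusted p = 0.281 with an estimated correlation). The mitotic kinases Aurka, Aurkb and Melk fell by 2.33 ± 0.19, 2.32 ± 0.16 and 1.83 ± 0.23. The nucleotide synthesis genes Tk1 and Rrm2 fell by 1.93 ± 0.18 and 1.44 ± 0.19, and the primase Prim1 by 1.49 ± 0.14. Of 18 glycolysis genes 1 rose and 11 fell (4.0e-04, adjusted p = 0.154 with an estimated correlation), including Pkm (-2.67 ± 0.21), Hk2 (-1.33 ± 0.18), Pdk1 (-1.32 ± 0.18) and Pgk1 (-1.29 ± 0.13). Of 35 ribosome biogenesis genes 18 rose and 2 fell (19 and 4, 4.0e-04, adjusted p = 0.380 with an estimated correlation), including the nucleolar genes Nop58 (1.53 ± 0.34), Nolc1 (1.49 ± 0.16), Ddx21 (1.19 ± 0.14) and Noc2l (1.16 ± 0.16).

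Smaller shifts passed camera and then failed with single arrays left out. Of 31 Hox genes and cofactors 0 rose and 8 fell (0.0391, adjusted p = 0.532 with an estimated correlation), including Hoxa10 (-2.24 ± 0.27), Hoxb5 (-1.98 ± 0.21), Hoxa9 (-1.82 ± 0.18) and the cofactor Meis1 (-1.62 ± 0.19). The Hox list did not pass without HSC replicate 2 (0.0537) or PreMegE replicate 3 (0.0983), or with PreMegE replicates 3 and 4 averaged as 1 sample (0.0566). Of 24 granulocyte-monocyte genes 3 rose and 9 fell (3 and 11, 0.0447, adjusted p = 0.532 with an estimated correlation), including the protease Prtn3 (-3.16 ± 0.30) and the repressor Gfi1 (-2.19 ± 0.24), while Cst7, a protease inhibitor, rose by 2.69 ± 0.14. This list did not pass without HSC replicate 2 (0.179), PreMegE replicate 2 (0.0623), 3 (0.0570) or 4 (0.0576) or either CD4+ T cell array (0.0506), under quantile normalisation (0.0554), or with PreMegE replicates 3 and 4 averaged (0.0566). The Hox (0.0854), granulocyte-monocyte (0.0854), B cell (0.137) and macrophage (0.643) lists did not pass with HSC replicate 1 as the lone HSC array. Of 20 macrophage genes 1 rose and 8 fell (1 and 10, 0.0124, adjusted p = 0.532 with an estimated correlation). The lysozyme gene Lyz2 fell by 1.84 ± 0.17, and the iron exporter Slc40a1, which early red cells also use, rose by 2.14 ± 0.34. Of 23 B cell genes 0 rose and 6 fell (0.0184, adjusted p = 0.581 with an estimated correlation), including the antigen presentation gene H2-Aa (-3.61 ± 0.23) and Cd72 (-2.15 ± 0.16). HSC replicate 2 was compared with the mean of HSC replicates 1 and 3. It was more than 1 log2 unit higher for 10 of 17 mature neutrophil, 5 of 20 macrophage and 3 of 23 B cell genes. Replicate 3 could be high as well, with the macrophage gene Vcam1 at 3.61, 7.06 and 6.75 on HSC replicates 1 to 3. Without HSC replicate 2 the macrophage and B cell lists did not pass (0.0710 and 0.161). The B cell list did not pass without PreMegE replicate 3 (0.0570).

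The other lists did not pass between PreMegE and HSC. Of 23 imprinted genes 2 rose and 8 fell (adjusted p = 0.0506), with Ndn changed by -4.31 ± 0.15 and Cdkn1c by -3.57 ± 0.21. It passed without HSC replicate 1 (0.0329), MPP replicate 1 (0.0470) or 3 (0.0496), or PreMegE replicate 1 (0.0430) or 2 (0.0352). Polycomb and Trithorax genes had 13 of 39 higher and 8 lower (14 and 8, 0.0611), including the cofactor Jarid2 (1.93 ± 0.14, and 0.11 on probe sets without the suffixes _s_at and _x_at, adjusted p = 0.806) and Cbx6 (-2.03 ± 0.18), and passed without HSC replicate 3 (0.0234) or PreMegE replicate 1 (0.0235) or 2 (0.0352). Oxidative phosphorylation had 16 of 58 higher and 11 lower (19 and 11, 0.0714), led by Ndufa6 (1.83 ± 0.17), and passed without HSC replicate 1 (0.0276) or PreMegE replicate 3 (0.0493). Lymphoid priming had 5 of 24 higher and 7 lower (6 and 9, 0.455), including Cd48 (3.17 ± 0.25) and Ltb (-2.85 ± 0.20), both of lymphocyte signalling. T cell genes had 3 of 37 higher and 8 lower (4 and 8, 0.631), NK and cytotoxic genes 1 of 16 higher and 0 lower (0.8002, with a median of -0.03 and an upward test), and mature neutrophil genes 1 of 17 higher and 2 lower (0.8002). Mast cell, basophil and eosinophil genes had 1 of 15 higher and 0 lower (0.406), the mast cell protease Cpa3 (1.83 ± 0.20), and stroma and endothelium 2 of 19 higher and 1 lower (0.495). Cell-cycle inhibitors had 6 of 23 higher and 8 lower (7 and 8, 0.8002), with a median of 0.09 and a mean of -0.16. DNA methylation genes had 2 of 14 higher and 5 lower (0.599), interferon response genes 8 of 31 higher and 10 lower (10 and 10, 0.748), and developmental regulators 0 of 36 higher and 1 lower (0.748), with a median of 0.01 and a mean of -0.01. The sex-linked list had 1 of 4 higher and 2 lower (0.670), with a median of -1.19 and a mean of 0.04, from the Xist and Eif2s3y values of HSC replicates 2 and 3.

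Several of these genes read differently on their next brightest probe set. There Mmrn1 (-0.02), Mecom (-0.14), Itgb3 (-0.08), Slc40a1 (0.52), Prim1 (-0.32), Hoxa9 (-0.28), Pdk1 (-0.43), Cbx6 (-0.48) and Jarid2 (0.50) did not pass. Aurka (0.15) and Hoxa10 (0.04) had the opposite sign and were not called. The ribosome biogenesis genes Nolc1 (-1.15, adjusted p = 0.00748) and Noc2l (-0.85, 0.0166) were called in the opposite direction.

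The comparison of PreMegE with MPP sets the platelet and red cell path against the lymphoid and myeloid one. St8sia6 rose by 7.52 ± 0.34 (n = 4 against 3, adjusted p = 1.9e-10), Mfsd2b by 6.97 ± 0.18, Car1 by 6.57 ± 0.23, Ces2g by 6.56 ± 0.15, Klf1 by 6.52 ± 0.19 and Ermap by 6.41 ± 0.25. The immediate early genes Fosb (-7.79 ± 0.22), Klf4 (-7.74 ± 0.31), Fos (-7.63 ± 0.36) and Cxcl2 (-7.25 ± 0.28), the cytokine signalling inhibitor Socs3 (-6.69 ± 0.25) and Dntt (-7.57 ± 0.22) fell. For 4 of these 12 genes (St8sia6, Fosb, Klf4 and Cxcl2) the lower mean was under the lower quartile. Among regulators Gata1 rose by 4.70 ± 0.14, Gata2 by 1.81 ± 0.13 and Tal1 by 1.02 ± 0.16, while Cebpa (-2.53 ± 0.20) and Spi1 (-1.09 ± 0.20) fell. Of all genes 6004 (33.0%) were called, 2454 higher and 3550 lower in PreMegE, and 2644 differed at least 2-fold (957 higher and 1687 lower).

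Of 35 erythroid genes 26 rose and 0 fell (camera adjusted p = 6.4e-15, and 0.00994 with an estimated correlation). Of 24 lymphoid priming genes 3 rose and 15 fell (5 and 15, 2.7e-06, and 0.00994 with an estimated correlation), including Cd53 (-5.57 ± 0.22), Ighm (-5.13 ± 1.17) and Irf8 (-4.05 ± 0.23). Ighm was at 9.35 on PreMegE replicate 1 and at 3.57 to 4.36 on the other PreMegE arrays. Of 34 HSC-associated genes 4 rose and 23 fell (4 and 25, 4.8e-08, and 0.00994 with an estimated correlation), including Procr (-5.05 ± 0.14), Hlf (-4.96 ± 0.16) and Mecom (-4.71 ± 0.21). Of 27 immediate early and heat shock genes 1 rose and 25 fell (9.9e-22, and 0.0231 with an estimated correlation), the member that rose being the chaperone Hsph1 (9.77 to 10.10 in PreMegE and 9.15 to 9.39 in MPP). Of 24 granulocyte-monocyte genes 2 rose and 17 fell (2.7e-08, adjusted p = 0.0616 with an estimated correlation), including Emb (-5.78 ± 0.26), Mpo (-5.30 ± 0.55), Prtn3 (-4.68 ± 0.30) and Ctsg (-4.37 ± 0.39).

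Of 43 DNA replication genes 1 rose and 26 fell (1 and 28, 3.7e-06, adjusted p = 0.304 with an estimated correlation), including Uhrf1 (-1.63 ± 0.17), which guides DNA methylation at replication forks, and the polymerase Pole (-1.53 ± 0.21). Of 39 mitosis genes 2 rose and 24 fell (2 and 25, 1.6e-05, adjusted p = 0.524 with an estimated correlation), including Aurkb (-2.35 ± 0.16). Of 18 glycolysis genes 2 rose and 12 fell (2.0e-04, adjusted p = 0.110 with an estimated correlation), including Pkm (-3.44 ± 0.21), Hk2 (-2.05 ± 0.18) and Pgam1 (-2.02 ± 0.15). Of 20 macrophage genes 1 rose and 8 fell (0.0271, adjusted p = 0.524 with an estimated correlation), including Csf1r (-3.06 ± 0.30), while Slc40a1 rose by 3.20 ± 0.34. The macrophage list did not pass without PreMegE replicate 3 (0.0533). On their next brightest probe set Mecom (-0.12), Mylk (-0.61), Grb10 (0.28) and Hoxa9 (-0.61) did not pass between PreMegE and MPP.

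Megakaryocyte genes, 12 of 27 higher and 7 lower in PreMegE than in MPP, did not pass as a list (adjusted p = 0.174), and among them Mylk changed by -3.37 ± 0.24. Other lists that did not pass were T cell with 3 of 37 higher and 13 lower (0.108), B cell with 0 of 23 higher and 6 lower (0.0847) and NK and cytotoxic with 1 of 16 higher and 2 lower (0.888). Mature neutrophil genes had 6 of 17 higher and 2 lower (0.194), including Padi4 (-3.56 ± 0.25) and Chil3 (3.22 ± 0.67), and passed without HSC replicate 2 (0.0399). Mast cell, basophil and eosinophil genes had 3 of 15 higher and 1 lower (2 and 0, 0.194), with Cpa3 at 2.00 ± 0.20, and stroma and endothelium 3 of 19 higher and 1 lower (0.195). Cell-cycle inhibitors had 4 of 23 higher and 9 lower (5 and 9, 0.174), and imprinted genes 2 of 23 higher and 6 lower (0.563), with Ndn at -2.49 ± 0.15 and Grb10 at 2.41 ± 0.15. Hox genes and cofactors had 1 of 31 higher and 7 lower (0.420), with Hoxa9 at -2.28 ± 0.18, and developmental regulators 1 of 36 higher and 1 lower (0 and 1, 0.563). Polycomb and Trithorax genes had 8 of 39 higher and 4 lower (0.0665), with Jarid2 at 2.52 ± 0.14, and at 0.53 (adjusted p = 0.121) on probe sets without the suffixes _s_at and _x_at. They passed under quantile normalisation (0.00937), loess (0.00728), and without MPP replicate 3 (0.0463) or PreMegE replicate 1 (0.0188) or 2 (0.0360). DNA methylation genes had 4 of 14 higher and 4 lower (4 and 5, 0.847), oxidative phosphorylation 11 of 58 higher and 15 lower (0.899), interferon response 9 of 31 higher and 11 lower (0.815) and sex-linked genes 0 of 4 on either side (0.774). Of the 4 sex-linked genes Uty had the smallest p (0.44, adjusted p = 0.291). Ribosome biogenesis had 13 of 35 higher and 7 lower (0.134), with the growth regulator Myc at 1.44 ± 0.16, and passed under quantile normalisation (0.0332) and loess (0.0224).

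CD4+ T cells were compared with HSC as a mature blood cell. The T cell receptor segment Trbv1 rose by 9.65 ± 0.16 to 12.48 ± 0.22 (n = 2 against 3, adjusted p = 4.0e-15), Ms4a4b, a membrane protein of T cells, by 9.07 ± 0.28, and the receptor subunit Cd3g by 8.39 ± 0.18. The interleukin-7 receptor Il7r rose by 8.29 ± 0.23, the adhesion molecule Cd2 by 8.23 ± 0.18 and Cd5 by 8.22 ± 0.17. Falls included the transferrin receptor Tfr2 (-8.54 ± 0.17), the adaptor Bex1 (-8.44 ± 0.32), Hoxa9 (-8.42 ± 0.21), the Tie2 ligand Angpt1 (-8.40 ± 0.19), Meis1 (-8.11 ± 0.22) and the fatty acid enzyme Hacd1 (-8.04 ± 0.16). For 10 of these 12 genes, all but Ms4a4b and Il7r, the lower mean was under the lower quartile. Of all genes 6879 (37.8%) were called, 3096 higher and 3783 lower in T cells, and 4227 differed at least 2-fold (1904 higher and 2323 lower). The T cell arrays came from an earlier study and a sort that left out cells with B220. The B cell gene Ms4a1 was at 6.46 and 6.76 on them (2.66 to 3.42 in HSC) and the erythroid genes Alas2 and Slc4a1, chosen after their values were seen, at 7.43 and 9.35 and at 6.13 and 8.55. Slc4a1 was also at 6.94 on HSC replicate 2. Whether the B cell and erythroid transcripts on the T cell arrays, Ighm below included, came from the T cells or from other cells was not tested.

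Of 37 T cell genes 33 rose and 1 fell (camera adjusted p = 1.9e-33, and 3.7e-04 with an estimated correlation). Of 24 lymphoid priming genes 17 rose and 1 fell (17 and 3, 5.9e-09, and 0.00267 with an estimated correlation), including Cd53 (5.63 ± 0.27) and Ighm (6.12 ± 1.40), an antibody gene at 12.28 and 12.49 on these arrays, while the repressor Bcl11a fell by 5.62 ± 0.21. Of 34 HSC-associated genes 2 rose and 30 fell (2 and 31, 2.1e-22, and 3.7e-04 with an estimated correlation), including Ifitm1 (-6.91 ± 0.20) and the adhesion receptor Adgrg1 (-6.82 ± 0.22). Of 27 megakaryocyte genes 1 rose and 20 fell (2.0e-09, and 0.0102 with an estimated correlation), including Nfe2 (-5.88 ± 0.19), Vwf (-5.82 ± 0.24) and Pf4 (-5.63 ± 0.25). Of 43 DNA replication genes 0 rose and 39 fell (1 and 39, 1.8e-18, and 0.0348 with an estimated correlation), including the licensing genes Cdc6 (-5.10 ± 0.22) and Mcm10 (-4.00 ± 0.21). Of 39 mitosis genes 0 rose and 37 fell (9.4e-24, adjusted p = 0.0666 with an estimated correlation), including Aurkb (-4.87 ± 0.20), Kif2c (-4.85 ± 0.23) and Cdc20 (-4.65 ± 0.18).

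Of 35 erythroid genes 4 rose and 19 fell (5.4e-05, adjusted p = 0.105 with an estimated correlation), including Car1 (-6.34 ± 0.27) and Hemgn (-5.86 ± 0.17). Of 23 B cell genes 15 rose and 1 fell (8.6e-07, adjusted p = 0.177 with an estimated correlation), including the coactivator Pou2af1 (4.61 ± 0.27) and Ms4a1 (3.56 ± 0.20). The HSC means of Pou2af1 and Ms4a1 were under the lower quartile. Of 16 NK and cytotoxic genes 6 rose and 1 fell (0.00191, adjusted p = 0.263 with an estimated correlation), including the receptor Klrd1 (5.27 ± 0.34) and the chemokine Ccl5, which rose 16.0-fold. Of 31 interferon response genes 19 rose and 4 fell (20 and 4, 1.4e-04, adjusted p = 0.177 with an estimated correlation), including Ifit1 (2.84 ± 0.30) and Ifit3 (2.58 ± 0.21), while Oasl2 fell by 2.13 ± 0.21. Of 23 imprinted genes 4 rose and 11 fell (0.0159, adjusted p = 0.207 with an estimated correlation), including Grb10 (-6.18 ± 0.18) and Ndn (-5.31 ± 0.18). Of 31 Hox genes and cofactors 0 rose and 9 fell (0.0108, adjusted p = 0.391 with an estimated correlation), including Hoxa5 (-2.22 ± 0.27). Without CD4+ T cell replicate 1 neither the imprinted nor the Hox list passed (0.0661 and 0.0761). Of 58 oxidative phosphorylation genes 21 rose and 4 fell (0.00764, adjusted p = 0.537 with an estimated correlation), led by Ndufa6 (2.17 ± 0.20), and the list did not pass under quantile normalisation (0.0568).

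Lists that did not pass between CD4+ T cells and HSC included granulocyte-monocyte genes, with 7 of 24 higher and 12 lower (8 and 12, adjusted p = 0.430), among them Prtn3 (-5.49 ± 0.35) and Emb (4.60 ± 0.31). Macrophage genes had 7 of 20 higher and 2 lower (0.0979), with Mpeg1 at 2.94 ± 0.37, and passed without HSC replicate 2 (0.0176) and with HSC replicate 1 as the lone HSC array (0.00132). Mature neutrophil genes had 1 of 17 higher and 7 lower (1 and 8, 0.0922), with Ngp at -4.10 ± 0.78, and passed without HSC replicate 1 (0.0205) or 3 (0.0199). Mast cell, basophil and eosinophil genes had 0 of 15 higher and 3 lower (0.245), and stroma and endothelium 0 of 19 higher and 4 lower (0.167). Cell-cycle inhibitors had 9 of 23 higher and 7 lower (0.279), led by the antiproliferative genes Btg1 (3.42 ± 0.26) and Btg2 (3.25 ± 0.33). Polycomb and Trithorax genes had 14 of 39 higher and 8 lower (16 and 8, 0.279), with Kmt2c at 2.22 ± 0.30, and DNA methylation genes 1 of 14 higher and 5 lower (0.133), with Dnmt3b at -3.29 ± 0.31. Ribosome biogenesis had 9 of 35 higher and 15 lower (0.279), glycolysis 4 of 18 higher and 7 lower (5 and 7, 0.455, with a median of 0.04 and a mean of -0.42) and immediate early genes 8 of 27 higher and 9 lower (0.749), with Fosb at -4.97 ± 0.27 and Egr2 at 4.88 ± 0.21. Developmental regulators had 0 of 36 higher and 3 lower (0 and 1, 0.924), and the sex-linked list 1 of 4 higher and 2 lower (1 and 3, 0.472). Among regulators Gata3, which T cells require, rose by 2.43 ± 0.15, while Gata1 (-3.39 ± 0.17), Klf1 (-3.08 ± 0.23), Tal1 (-5.59 ± 0.19), Spi1 (-1.11 ± 0.24) and Ezh2 (-1.67 ± 0.17) fell. On its next brightest probe set Mcm10 (-0.57) did not pass and Grb10 gave 0.03.

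Genes highest in a single population numbered 109 in HSC, 220 in MPP, 236 in PreMegE and 991 in CD4+ T cells. Independent lists would share 3.64, 5.55, 3.89 and 17.1 genes, and 20 simulations of unchanged groups gave means of 0, 0, 0 and 0.05. Both baselines are small by construction, as the comparisons of a population share its arrays and the simulated groups had equal means. They do not test whether the genes belong to the population. HSC were set apart by Pf4, at least 4.02 above each other population on the log2 scale, by Mmrn1 (2.33), Fhl1 (2.15), the potassium channel Kcnk5 (2.15), Tgm2 (2.11) and the secreted protein Kazald1 (2.09). Eif2s3y and Kdm5d also entered, from HSC replicates 2 and 3 alone, and were under the lower quartile in all other populations. With the mean of all probe sets of a gene, 62 genes were highest in HSC. Of 34 HSC-associated genes 11 were highest in HSC, as were 6 of 27 megakaryocyte genes. MPP were set apart by Dntt (4.83), Ccl9 (4.83), Cxcl2 (4.58), Atf3 (4.29) and the receptor Cd244a (3.80). Ccl3, Bpifc and the germ cell helicase Ddx4 were at 8.61, 7.45 and 7.51 in MPP and under the lower quartile in all other populations. Of 27 immediate early genes 13 were highest in MPP, and of 24 granulocyte-monocyte genes 7. PreMegE cells were set apart by Gdpd3 (5.32), Zg16 (4.19), Ces2g (4.06), Scin (3.94), the dynein Dnah12 (3.85), the lectin Clec4d (3.83) and the translocator Tspo2 (3.79), and Rec114 was at 7.64 there and under the lower quartile elsewhere. Of 35 erythroid genes 11 were highest in PreMegE. CD4+ T cells were set apart by Ms4a4b (7.96) and the T cell factor Bcl11b (7.70). Trbv1, Cd3g, Cd2, Cd5, the homing receptor Ccr7 and the signalling protein Rasgrp1 were at 12.48, 10.97, 11.06, 10.94, 10.96 and 10.84 there and under the lower quartile in all other populations. The T cell list had 32 of 37 genes highest there and the B cell list 11 of 23. Whether the B cell transcripts came from the T cells themselves was not tested.

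**Figure D4:**
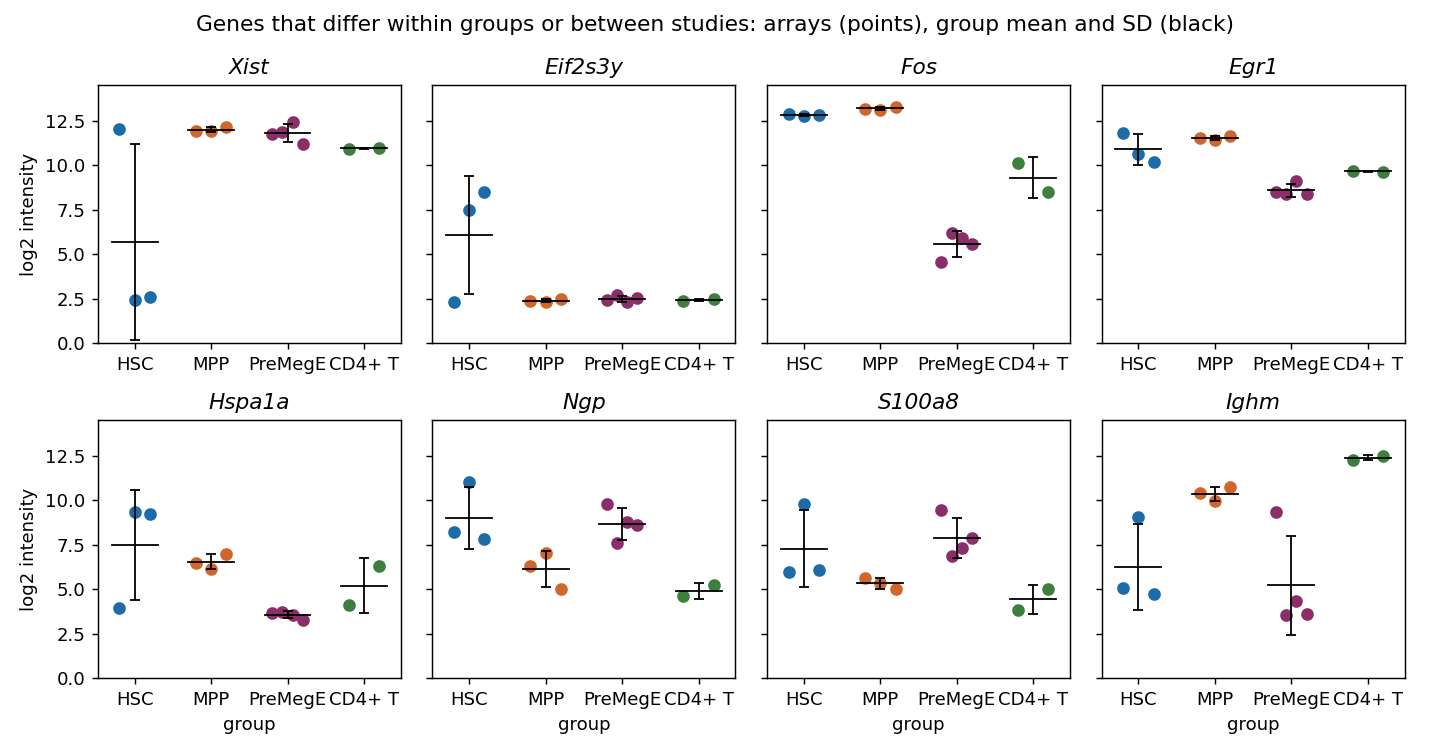
Log2 intensity on each array (points) with group means and SD bars for 8 genes that differed between arrays of a group or between studies. HSC replicates 2 and 3 had Xist at 2.45 and 2.59 and Eif2s3y at 7.46 and 8.47, and HSC replicate 2 had Ngp at 11.01.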

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

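In PreMegE, the population with 4 arrays, the named genes, the list medians and 5 array quality values were tested for a single array apart from the rest, a test fixed before the data were examined. Of 243 such groups 14 had a Dixon ratio above the critical value for 4 arrays, and chance alone marks about 1 in 20 groups.

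On PreMegE replicate 1 the immunoglobulin gene Ighm was at 9.35 against a mean of 3.85 on the other 3 arrays (ratio 0.863), and the protease Ctsg at 6.03 against 4.37 (0.877). The same array had Klrd1 at 3.31 against 3.01 (0.854) and Uqcrfs1 at 9.51 against 9.96 (0.870). On PreMegE replicate 3 the spindle gene Racgap1 was at 6.75 against 5.73 (0.858), St8sia6 at 11.30 against 10.50 (0.838), Egr1 at 9.13 against 8.40 (0.840) and Scin at 10.31 against 9.76 (0.839). That array also had Myc at 9.94 against 9.46 (0.873), Cst7 at 8.31 against 8.61 (0.837) and Zg16 at 9.97 against 10.61 (0.873), and its median over the developmental regulators was 3.08 against 3.34 (0.830). Spi1 was at 5.32 on replicate 2 against 5.63 (0.890), and Trbv1 at 2.53 on replicate 4 against 2.62 (0.866).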

How the results depend on the processing

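Most alternatives were fixed before the data were examined. The fits with HSC replicate 1 as the lone HSC array, without genes of chromosomes X and Y, and without HSC replicate 2 and PreMegE replicate 1 were chosen after results were seen. Where a cause is not given, the cause was not tested.

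For 361 named gene results 8818 alternatives gave 8520 unchanged readings, 256 weaker, 10 stronger and 32 reversed. For 104 list results 2592 alternatives gave 2447 unchanged, 88 weaker, 57 stronger and 0 reversed. The next brightest probe set reversed 22 gene results, weakened 45, strengthened 2 and left 129 unchanged. Leaving out 1 array weakened 111 and strengthened 3. A reading counted as unchanged when its sign and call stayed, or when its sign changed and neither fit called it. Some alternatives could barely change a gene result. Leaving out genes of the X and Y chromosomes left all 342 readings unchanged, and leaving out the lowest genes all 346. The totals are therefore no measure of robustness.

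The next brightest probe set reversed these genes in MPP against HSC, namely Hnf4a (-0.39), Asxl1 (0.22), Nolc1 (-0.46), Ikzf1 (-0.021) and Eif2s3y (0.031). In PreMegE against HSC it reversed Kit (1.03), Slamf1 (0.79), Anxa1 (0.21), Aurka (0.15), Hoxa10 (0.041), Hnf4a (0.023), Mbd2 (-0.35), Nolc1 (-1.15), Noc2l (-0.85), Eif2s3y (0.0064), Bmi1 (-0.36) and Ikzf1 (-0.14). In PreMegE against MPP it reversed Hoxa10 (0.15) and Hnf4a (0.41), and in CD4+ T cells against HSC Grb10 (0.029), Eif2s3y (0.18) and Pax5 (0.25). Among these reversals, Kit, Slamf1, Nolc1 and Noc2l in PreMegE against HSC were also called on that probe set. Of 361 named gene results 198 had further probe sets. Any of these was called the same way for 127 results and the opposite way for 7. Probe sets without the suffixes _s_at and _x_at gave the same 3 values for Hnf4a (-0.39, 0.023 and 0.41). The mean of all probe sets gave 0.024 for Dnmt3a in PreMegE against HSC, and 62 genes highest in HSC, of which 58 were among the 109.

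With HSC replicate 1 as the lone HSC array 779 genes were called in MPP against HSC (725 shared) and 3395 in PreMegE against HSC (3238 shared). Xist then gave -0.041, -0.24 and -1.09 in MPP, PreMegE and CD4+ T cells against HSC, and Eif2s3y 0.082, 0.19 and 0.13. This array alone carried HSC Xist, so the sign change follows from the construction.

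Counting each probe set on its own gave 3340, 9309, 11784 and 13224 calls in MPP against HSC, PreMegE against HSC, PreMegE against MPP and CD4+ T cells against HSC. It gave 175, 472, 519 and 2249 highest in HSC, MPP, PreMegE and CD4+ T cells. A gene with several probe sets is then counted several times. A 2-fold minimum left 855, 2095, 2644 and 4227 genes. With an estimated correlation 6, 1, 4 and 5 lists passed, against 11, 12, 9 and 13.

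Leaving out each array in turn gave 1280 to 2341 genes in MPP against HSC, 4264 to 5436 in PreMegE against HSC, 4861 to 6412 in PreMegE against MPP and 5797 to 7149 in CD4+ T cells against HSC. Genes highest in HSC, MPP, PreMegE and CD4+ T cells numbered 96 to 114, 202 to 225, 224 to 263 and 966 to 1068. Lists that passed numbered 9 to 14, 8 to 14, 8 to 10 and 11 to 14.

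With the replicate number as a replicate block 2153, 5034, 5800 and 7113 genes were called, and 12, 11, 9 and 14 lists passed. Only 1 of 3 HSC arrays correlated best with the MPP array of its own number (-0.00456, 0.156 and 0.0694), so the numbers were not treated as paired.

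With PreMegE replicates 3 and 4 averaged as 1 sample 2295, 5180, 6050 and 7139 genes were called, with 2052, 4917, 5714 and 6869 shared. Of the list results 3 were weaker, namely mature neutrophil in MPP against HSC (adjusted p = 0.0571) and Hox and granulocyte-monocyte in PreMegE against HSC (0.0566 each). Of the gene results 2 were weaker, namely H2-Aa in MPP against HSC (0.0503) and Flt3 in PreMegE against HSC (0.0508).

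HSC replicate 2 and PreMegE replicate 1 were left out together because of mature neutrophil genes. Over these genes they lay above the mean of the other arrays of their group by medians of 1.33 and 0.49. Their deviations from the group means correlated at 0.439. Other pairs had similar sizes, with 0.413 for HSC replicate 3 with PreMegE replicate 3 and -0.453 for HSC replicate 2 with PreMegE replicate 3. Upper quartiles were 63.9 on HSC replicate 2 and 63.0 on PreMegE replicate 1, against 76.3 on HSC replicate 3 and 80.2 on PreMegE replicate 3. The correlation therefore does not show a shared content of mature cells. Without HSC replicate 2 and PreMegE replicate 1, calls numbered 1550, 4208, 5659 and 6477, with 1421, 4048, 5389 and 6218 shared. Among gene results 14 were weaker, and among list results 7 were stronger and 6 weaker. The first number for each list is the mean change of its members minus that of the other genes. In PreMegE against MPP the B cell (-0.49) and mature neutrophil (0.61) lists passed (adjusted p = 0.0447 each), as did Polycomb and Trithorax (0.38, 0.0165). In PreMegE against HSC the imprinted list passed (-0.62, 0.0478), while granulocyte-monocyte (-0.49, 0.0555) and B cell (-0.37, 0.0892) did not. In MPP against HSC the T cell (0.42, 0.0200) and mitosis (-0.21, 0.0128) lists passed. Mature neutrophil (-0.26, 0.396), cell-cycle inhibitors (0.56, 0.0711), ribosome biogenesis (0.16, 0.0792) and oxidative phosphorylation (0.12, 0.0709) did not. In CD4+ T cells against HSC macrophage genes passed (0.70, 0.0184).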

Other observations

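The gene families and the tests of explanations here were chosen after results were seen, except the 3 tests of array splits. Scaling was checked gene by gene only for the called genes with the largest change, up to 5 per family and comparison. Of these 174 values 0 changed sign under quantile normalisation or cyclic loess, and 2 were no longer called. The counts below also cover the other members and changed more. The families and comparisons below were picked from a larger set. In MPP against HSC, where 11.3% of all genes were called, Toll-like receptor genes had 1 of 11 higher and 0 lower. TNF receptor genes had 1 of 19 and 0, Rgs genes 3 of 21 and 1, and Sox and Klf genes 8 of 35 and 3. Solute carriers had 17 of 320 higher and 12 lower.

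Of 31 chemokine genes 6 rose and 0 fell in MPP against HSC, under both scalings too. After Ccl3 (5.41), Ccl9 (5.02) and Cxcl2 (4.58) these included Ccl4 (2.39) and Cxcl10 (1.14), which recruit leukocytes. Of 36 interleukin receptor genes 7 rose and 0 fell, with 6 and 0 under quantile normalisation, led by Il1r1 (2.07), Il7r (1.83) and Il18rap (1.40). In PreMegE against MPP 2 rose and 15 fell, with 3 and 17 under quantile normalisation and 3 and 16 under loess, and Il1r1 changed by -3.06.

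Of 8 Gimap GTPase genes, known for lymphocyte survival, 8 rose in CD4+ T cells against HSC, among them Gimap4 (6.86) and Gimap7, whose mean in HSC was under the lower quartile. In PreMegE against HSC 6 fell, with 4 under quantile normalisation and 5 under loess, led by Gimap8 (-4.11). Of 14 chemokine receptor genes 7 rose and 0 fell in CD4+ T cells, among them Ccr7 (7.87), Cxcr3 (5.87) and Cxcr5 (5.47). The HSC means of Ccr7 (3.08) and Cxcr5 (2.86) were under the lower quartile, so their differences are not exact folds. Of 29 integrin genes 11 rose and 1 fell, with 10 and 1 under quantile normalisation and 12 and 1 under loess, with Itgb7 at 5.53 and Itga2b at -5.45.

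Regrouping the arrays asked whether an arbitrary division could give as many called genes. In MPP against HSC the real split gave 2058 and the highest other split 0, so 1 of 10 splits reached the real count, and 10 splits cannot give a share under 0.05. In PreMegE against HSC 1 of 35 splits reached 5255, with 2250 as the highest other. That split was the real division with PreMegE replicate 3 moved to the HSC arrays. Moving PreMegE replicate 1, 2 or 4 instead gave 13, 0 and 0. In PreMegE against MPP 1 of 35 splits reached 6004, with 3086 as the highest other, again with PreMegE replicate 3 moved. Moving PreMegE replicate 1, 2 or 4 to the MPP arrays gave 0 each. In the latter pair of comparisons 1 of 35 is a share under 0.05, which makes an arbitrary division unlikely if all arrays are separate samples. A difference between the studies would give the same result, so the splits do not show that cell type is the cause. The labels leave open whether PreMegE replicates 3 and 4 are separate samples. With them as 1 sample the splits would be too few.

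Of 27 immediate early and heat shock genes 19 were higher in MPP than in HSC and 25 lower in PreMegE than in MPP, and heat shock members were not called in MPP against HSC. Hspa1a was at 6.14 to 6.99 in MPP, below HSC replicates 2 and 3 (9.34 and 9.20) and above HSC replicate 1 (3.92). With HSC replicate 1 alone as the reference the median MPP excess was 1.24, against 1.69 with all HSC arrays, and as 1 array it does not exclude a state of HSC replicates 2 and 3. All MPP arrays lay above all HSC arrays for 20 of 27 members (chance gives 5% of genes), and all PreMegE arrays below all HSC arrays for 23 (chance gives 2.86%). Handling that differed between sorts, and for PreMegE the earlier study, could each give such values and are left open.

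HSC replicates 2 and 3 carried Y-linked transcripts, and their Xist lay 8.32 below the lowest other array, in line with male animals as their source. Against HSC replicate 1, which carried Xist as all MPP arrays did, 756 autosomal genes were called in MPP, of which 707 were among the 2001 called with all HSC arrays. A single array excludes nothing, so sex could be a cause of genes called in MPP against HSC and stays open. X and Y genes made up 2.77% of the called and 3.44% of the tested genes. Strain, age or sort differences between the HSC samples were not analysed here.

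HSC replicate 2 exceeded the mean of HSC replicates 1 and 3 by a median of 1.33 over 17 mature neutrophil genes. Genes below the median level shifted by 0.141 and HSC-associated genes by a median of -0.06, so these sets did not share the excess. RMA brings arrays to a common scale, which would largely remove a uniform shift of the whole array beforehand. These values therefore do not test such a shift. They also cannot exclude an array-wide change in spread. The lower quartile of intensity was 8.53 on HSC replicate 2, against 8.11 and 7.85 on replicates 1 and 3. Its upper quartile was 63.9 against 72.2 and 76.3, and mitosis genes had a median of -0.25 and Polycomb and Trithorax genes of -0.21. RNA of mature neutrophils in the sample could give the excess, although the lineage-negative gate would remove such cells. Anxa1 (0.19) and Padi4 (-0.65) did not share it. Other cell types moved on the same array too, with medians of 0.52 over macrophage and 0.47 over B cell genes. Ighm was at 9.04 (5.04 and 4.71 on replicates 1 and 3), Slc4a1 at 6.94 (2.92 and 4.25) and Alas2 at 5.53 (3.26 and 3.49). The erythroid list as a whole had a median of 0.04 there, with 2 of 35 members more than 1 log2 unit above the mean of replicates 1 and 3. RNA of a mix of mature cells stays open.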
